A study of Caenorhabditis elegans with 43 samples.

How the data were processed

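Ribosome-protected mRNA fragments were sequenced from whole Caenorhabditis elegans animals sampled every 2 h during larval development, in 43 libraries from 4 strains. Per the labels, the strains were wild type N2, let-7(n2853), lin-41(xe11) and the double mutant lin-41(xe11); let-7(n2853). The let-7(n2853) animals made a first time course of 10 libraries, from 18 to 36 h after feeding of synchronised L1 larvae. The other 3 strains made a second time course of 11 libraries each, from 18 to 38 h. Per the labels' protocols, monosomes were purified on sucrose density gradients in the first course and by size-exclusion chromatography in the second. Strain let-7(n2853) is therefore confounded with the time course and the purification, and there is 1 library per strain and hour.

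The authors deposited a table of footprint counts for 20182 genes and a second table of normalized log2 values. Per the submitters' processing notes, reads were mapped with Bowtie. Its version, the genome build, the annotation and the treatment of reads that map to more than 1 place were not given in the sources used here. Values of near-identical paralogs (collagens, vitellogenins, histones, insulin-like genes, nsph and msrp genes) are uncertain for that reason. The deposited log2 values equalled log2 of the scaled count plus 8, with each library scaled to a total of 26096086 in the first course and of 12019637 in the second (relative spread 7e-09, as computed here from the 2 tables). The tests used the deposited counts, and the deposited log2 table served as an alternative.

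Gene identifiers were joined to symbols by exact match to a name table; 18778 had a symbol and 1404, with 1.04% of the counts, had none. Of all identifiers 19513 were present in the WBcel235 annotation, from which gene positions were taken; 189 rows had an ambiguous symbol. Depth ran from 5020197 to 12361022 counts per library in N2 and from 7040947 to 12551598 in lin-41(xe11). It ran from 6133302 to 12797339 in the double mutant and from 17364056 to 32261888 in let-7(n2853). The 10 most counted genes of a library held from 6.0 to 7.85% of its counts, and over all libraries eef-1A.1 held 1.358%, unc-54 0.86% and eef-2 0.672%. No pair of libraries was identical, and the highest correlation between 2 libraries was 0.9915.

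The following choices were made before the data were examined: the windows, filters, tests, gene lists, named-gene rule and a list of alternatives. The early window held 18 to 24 h (4 hours) and the late window 28 to 36 h (5 hours); 26 h lies between the windows and 38 h is lacking in let-7(n2853), and both were left out of the edgeR comparisons of the windows. The rhythm fits used 18 to 36 h, 26 h included, and the wider windows and a rhythm alternative among the alternatives below, and a test of delay in the closing section, used 38 h. Counts were fitted with edgeR 4.0.16 (quasi-likelihood, TMM factors, genes with at least 1 CPM in at least 5 libraries) in R 4.3.3, with a term for each hour and one for each strain in each window. N2, lin-41(xe11) and the double mutant were fitted together (27 libraries, 14 residual degrees of freedom). N2 and let-7(n2853) were fitted together (18 libraries, 7 residual degrees of freedom), and the difference of differences, late minus early, was tested, so that any constant offset between the 2 time courses is removed. N2 late against early was fitted on N2 alone, with no hour term. Genes with a Benjamini-Hochberg adjusted p under 0.05 are called. Hours of a window stand in for replicates, so the p-values measure only the spread between hours and not that between independent cultures. CPM are scaled by TMM library sizes, and errors of log2 values are standard errors of the fit.

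A set of 26 gene lists was written from general knowledge before the data were examined and tested with camera of limma 3.58.1, with a preset correlation of 0.01 and, beside it, with an estimated correlation; p-values were adjusted over the lists. Fixed lists also received an adjustment over the list alone. Genes of the main comparisons are named in the text by a fixed rule. Outside it, all genes called in let-7(n2853) late minus early, and in the early window of lin-41(xe11) and of the double mutant, are named, since they are few. It holds lin-41 and all members of the lists of LIN41 direct targets and of let-7 family candidate targets. It adds the 10 highest and the 10 lowest log2 fold changes among genes called in a comparison, with a mean of at least 5 CPM, a symbol of letters, hyphen and number, and 1 sign at all 5 late hours (the last condition does not apply within N2). Up to 4 members with the smallest p were named for a list that passed. Developmental age was estimated by correlation to the interpolated N2 course. Rhythms with a period of 8 h were fitted per gene with limma.

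The 5 main edgeR comparisons and the rhythm fit in N2 were tested on simulated data, drawn from the means and library sizes of the real libraries with 200 changed genes. The list test was tested with 1 changed list and the age estimate on simulated libraries; the other tests had no simulation of their own. Of genes changed 2-fold and 4-fold, 73 and 96% were recovered for lin-41(xe11) against N2, 87 and 96% for the double mutant against N2, and 78 and 95% for lin-41(xe11) against the double mutant. The let-7(n2853) difference of differences recovered 47 and 80%, and N2 late against early 47 and 84%, so the last 2 are the least precise. Of the calls, 4, 4.2, 2.3, 5.9 and 7.1% fell on unchanged genes, in the same order. The simulated libraries were drawn independently, without correlation between genes and, within N2, without a trend over the hours. Real hours follow each other in a time course, so these shares do not give the error rate of the real calls. The rhythm test recovered 0 of 200 genes of log2 amplitude 0.5 and 123 of 200 of amplitude 1, and estimated ages were off by at most 0.3 h.

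Alternatives covered scaling (RLE, library totals), filters, DESeq2 1.42.0, the deposited log2 table with limma, a fit without the hour term, other windows, all 4 strains in one fit, matching by estimated age, other rhythm settings and leaving out each hour in turn. Leaving out 34 and 36 h together, and each early hour for the comparisons that use the early window, was chosen after the data were seen. Tables were handled with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9. Other data types of these animals were not used here.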

Results

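Ribosome footprints were counted in 43 libraries of C. elegans, 11 each of N2, lin-41(xe11) and the double mutant lin-41(xe11); let-7(n2853), and 10 of let-7(n2853), at 1 library per strain and hour. The early window (18 to 24 h, 4 libraries per strain) lies before the fall of lin-41 in N2, and the late window (28 to 36 h, 5 libraries per strain) after it. The allele n2853 is a point mutation in the let-7 microRNA seed, and xe11 changes the let-7 complementary sites in the lin-41 3′ untranslated region. The 2 mutations compensate each other, so that pairing of let-7 to lin-41 is restored in the double mutant while other let-7 targets remain mismatched. Values are log2 fold changes ± standard error unless stated, and adjusted p-values come from edgeR quasi-likelihood tests.

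The gene targeted by the design, lin-41 (chromosome I, 9334800 to 9342496, WBcel235), encodes a TRIM-NHL RNA-binding protein repressed by let-7. Its early level was 59 ± 7.64 CPM in N2 (mean ± SD, n = 4), 64.3 ± 2.78 in lin-41(xe11), 65 ± 3.9 in the double mutant and 70.9 ± 7.29 in let-7(n2853). Its late level (n = 5) was 10 ± 5.37 CPM in N2, 31.5 ± 9.74 in lin-41(xe11), 28 ± 5.59 in the double mutant and 59.3 ± 5.12 in let-7(n2853). In the late window lin-41 rose over N2 3.02-fold in lin-41(xe11) (1.60 ± 0.24, adjusted p = 0.00256) and 2.69-fold in the double mutant (1.43 ± 0.24, adjusted p = 0.00428). Between lin-41(xe11) and the double mutant the difference was 0.17 ± 0.22 (adjusted p = 1), so full repression of lin-41 was not seen in the double mutant. The late minus early difference of let-7(n2853) to N2 was 2.36 ± 0.34, with adjusted p = 0.109. At 32 h lin-41 stood at 6.35 CPM in N2, 34.3 in lin-41(xe11) and 25.2 in the double mutant, and at 38 h at 42.8, 56.5 and 43.3. Leaving out any single late hour ended neither of the 2 lin-41 calls. Without 34 and 36 h the values were 2.49 (adjusted p = 4.24e-08) in lin-41(xe11), 2.16 (adjusted p = 3.03e-07) in the double mutant and 2.99 (adjusted p under 0.05) in let-7(n2853).

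**Figure D1:**
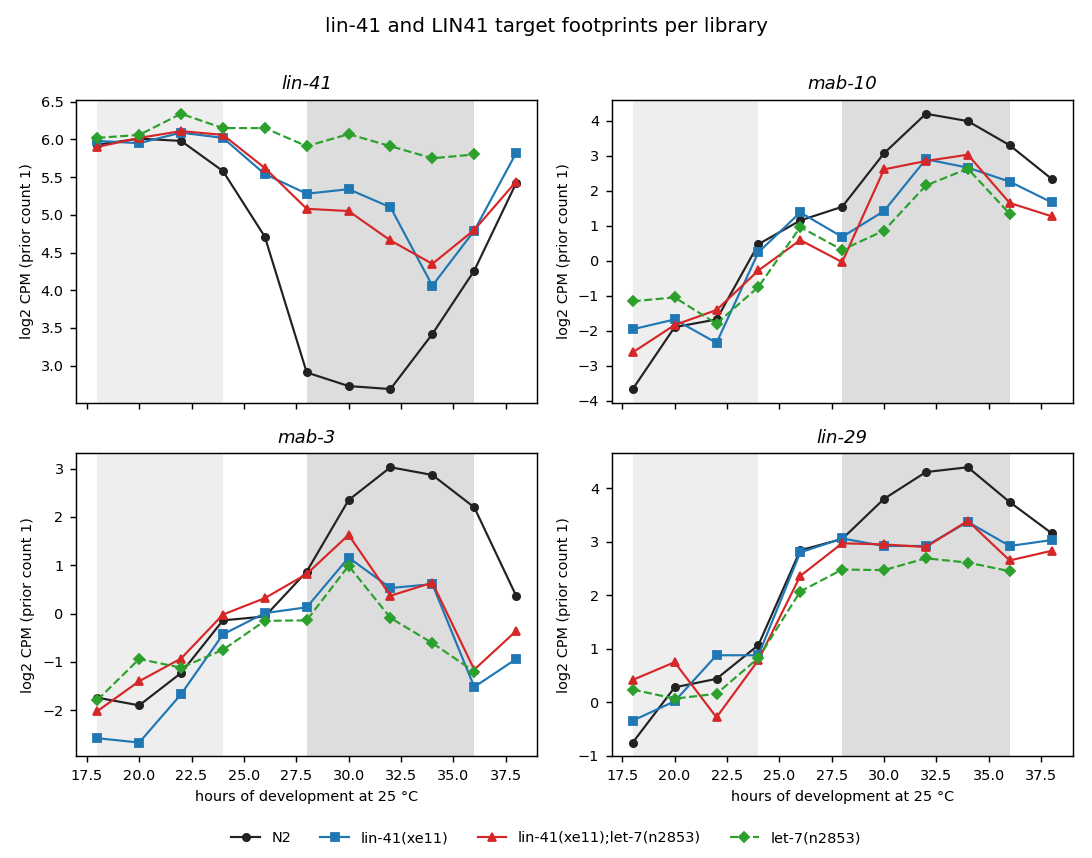
Footprint levels of lin-41, mab-10, mab-3 and lin-29 in each library, as log2 CPM against the hour. Light shading marks the early window and dark shading the late window; let-7(n2853), dashed, comes from the other time course.

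Within N2, the heterochronic genes lin-41 (−2.53 ± 0.36, adjusted p = 0.00908), daf-12 (−2.54 ± 0.26, adjusted p = 0.0053) and hbl-1 (−2.57, adjusted p = 0.00908) fell from the early (n = 4) to the late window (n = 5). The gene daf-12 encodes a nuclear receptor, and the zinc finger factor hbl-1 promotes larval fates. The zinc finger factor lin-29, which drives the larval-to-adult switch, rose by 3.64 ± 0.44 (adjusted p = 0.00558). Other genes that fell were the tubulin tba-8 (−3.33, adjusted p = 0.0388), the astacin protease nas-3 (−2.73, adjusted p = 0.0114), clec-42 (−2.11, adjusted p = 0.0236) and the insulin-like genes ins-4 (−2.0, adjusted p = 0.0114) and ins-5 (−1.79, adjusted p = 0.0168). The ABC transporters pgp-6 (−1.98, adjusted p = 0.0234) and pgp-5 (−1.87, adjusted p = 0.0338) fell as well. Among the genes with the highest rise, the adult cuticle collagen bli-1 went from 0.634 to 886 CPM (adjusted p = 0.018) and col-138 from 1.07 to 2200 (adjusted p = 0.0187). The spermatogenesis Argonaute alg-4 went from 0.0184 to 86.2 CPM (adjusted p = 0.0124), the sperm phosphatase gsp-3 from 0.0297 to 39.8 (adjusted p = 0.0147), catp-4 from 0.0764 to 55.9 (adjusted p = 0.0168) and nsph-3.2 from 0.029 to 151 (adjusted p = 0.0146). Counts were 0 in all 4 early libraries for msrp-2 (late 131 CPM, adjusted p = 0.0375), ttbk-4 (17.7, adjusted p = 0.0338), elo-7 (14, adjusted p = 0.0238) and the histone his-70 (13.2, adjusted p = 0.0209).

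In all, 1944 of 11806 genes were called between the N2 windows, 984 higher and 960 lower late. Among gene lists, 19 of 24 germline genes rose (median 1.41, adjusted p = 1.38e-14), among them prg-1 (1.06), pgl-3 (2.46) and syp-2 (2.84). Ribosomal protein genes rose in 71 of 76 cases (median 0.67, adjusted p = 7.82e-31). So did spermatogenesis genes such as fer-1 and spe-44 in 5 of 6 (adjusted p = 2.68e-06). The LIN41 direct targets rose in 3 of 3 (median 3.70, adjusted p = 0.000492) and translation factors in 7 of 17 (adjusted p = 0.000492), with the germline factors ife-5 (2.80) and iff-1 (2.06). Neuronal genes fell in 14 of 18 cases (median −0.72, adjusted p = 3.26e-09), with the GABA genes unc-25 (−1.08) and unc-47 (−1.24). Levels are shares of the counts of whole animals, so such a fall does not give the change per cell. Of 10 let-7 family candidate targets 4 fell (adjusted p = 0.00163), and the heterochronic list held 2 risen and 4 fallen genes (adjusted p = 0.031). Each of these 8 lists had an adjusted p = 0.268 with an estimated correlation. Adult epidermal genes rose in 4 of 6 cases (adjusted p = 0.00699; adjusted p = 0.373 with an estimated correlation). Of 11 seam cell genes egl-18 (−1.27), elt-1 (−1.09) and bro-1 (−2.25) fell and the fusogen aff-1 rose (1.72) (adjusted p = 0.00944; adjusted p = 0.373 with an estimated correlation). Pharyngeal genes fell, with phat-5 at −3.62 (adjusted p = 0.031; adjusted p = 0.413 with an estimated correlation). Oocyte and eggshell genes rose in 2 of 7 cases (adjusted p = 0.0144; adjusted p = 0.413 with an estimated correlation), and 2 intestinal genes rose (adjusted p = 0.0421; adjusted p = 0.373 with an estimated correlation). The count of calls was 633 without 18 h, 1002 without 20 h, 972 without 22 h, 1272 without 32 h, 964 without 34 h and 1004 without 36 h. The calls of lin-41, daf-12, hbl-1, nas-3 and ins-4 held in each of these fits. Those of msrp-2 and ttbk-4 did not hold in any of the 4 fits that tested them. Without 18 h the calls of bli-1 (adjusted p = 0.0606), col-138 (0.0622), alg-4 (0.0672), elo-7 (0.0598), his-70 (0.0551), catp-4 (0.0588), tba-8 (0.0988), clec-42 (0.0724), pgp-6 (0.0666) and ins-5 (0.0549) ended. Without 22 h those of nsph-3.2 (0.0721) and pgp-5 (0.0944) ended, and gsp-3 lost its call without 24 h (0.0616).

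In lin-41(xe11), the 3 measurable genes listed as direct targets of LIN41 repression fell against N2 in the late window (n = 5 libraries per strain). The lin-29 cofactor mab-10 (chromosome II, 10528084 to 10534380) fell by −1.27 ± 0.19 (adjusted p = 0.002), from 11 CPM in N2 to 4.48. The doublesex-family gene mab-3 (II, 9732137 to 9738035) fell by −2.16 ± 0.34 (adjusted p = 0.00347), from 5.32 to 1.25 CPM. The gene lin-29 (II, 11917642 to 11935343) fell by −0.87 ± 0.17 (adjusted p = 0.0191), from 15.2 to 8.2 CPM. As a list they passed in both list tests (adjusted p = 1.12e-06, and 0.00707 with an estimated correlation). General knowledge of LIN41 targets may rest in part on these same libraries, and this was not checked. The tests of this list, here and in the other comparisons, are therefore no independent support. The target dmd-3 was below the count filter (0.619 CPM in late N2). Of the let-7 family candidate targets only lin-41 was called: daf-12 stood at −0.07 (adjusted p = 0.952) and hbl-1 at 0.35 ± 0.13 (adjusted p = 0.641), and let-60, lin-28, lin-14, pha-4, die-1, nhr-23 and nhr-25 were not called (list adjusted p = 0.0966; 0.186 with an estimated correlation).

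Cuticle collagens made up most of the lowest genes in lin-41(xe11): col-60 (−4.20 ± 0.49, adjusted p = 0.000209), col-184 (−3.99 ± 0.63, adjusted p = 0.00375), col-122 (−3.70 ± 0.64, adjusted p = 0.00837), col-175 (−3.17 ± 0.30, adjusted p = 8.95e-05), bli-1 (−2.66 ± 0.29, adjusted p = 8.95e-05). Others were col-63 (−2.30 ± 0.31, adjusted p = 0.001), col-124 (−2.25 ± 0.43, adjusted p = 0.0183), col-38 (−2.08 ± 0.39, adjusted p = 0.0183) and col-71 (−1.76 ± 0.33, adjusted p = 0.0163). No list of all collagens was tested. Without both 34 and 36 h the values of col-184 (−0.67), col-122 (−0.20) and col-124 (−0.48) nearly vanished (each adjusted p = 1). Matched by estimated age, with limma, col-60 stood at −1.85 and was not called. The roller gene rol-1 fell by −2.24 ± 0.31 (adjusted p = 0.001). In late libraries col-60 averaged 240 CPM in N2 and 13.4 in lin-41(xe11). The strut collagen gene bli-1 of the adult cuticle reached 1940 CPM in N2 and 416 in lin-41(xe11) at 34 h. Of 7 adult epidermal genes 5 fell (median −2.08, adjusted p = 1.12e-06; adjusted p = 0.103 with an estimated correlation), with the adult-specific collagen col-19 at −2.12 (adjusted p = 0.00647) and col-49 at −1.98 (adjusted p = 0.0233), and 6 passed when adjusted over the list alone. Against these, bli-2 (−0.84, adjusted p = 0.252) and col-62 (−0.21, adjusted p = 0.918) were not called. Genes that rose were the ABC transporter pgp-5 (1.92 ± 0.38, adjusted p = 0.0281), the mitochondrial import subunit timm-17B.2 (0.75 ± 0.10, adjusted p = 0.00117) and the Furry homolog sax-2 (0.27 ± 0.05, adjusted p = 0.0191). Their early means were above N2 as well, though none was called. They were 3.45 against 1.75 CPM for timm-17B.2 (0.94 ± 0.18, adjusted p = 0.0916), 54.2 against 47.9 for sax-2 (0.17, adjusted p = 0.604) and 22.9 against 13.3 for pgp-5 (0.64, adjusted p = 0.95).

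In all, 56 of 13508 genes were called in lin-41(xe11), 9 higher and 47 lower. The count was 33 without 32 h, 13 without 34 h, 15 without 36 h and 5 without both 34 and 36 h. It was 17 when matched by estimated age, 16 from the deposited log2 table, 3 without the hour term and 138 with wider windows. Calls of lin-41, timm-17B.2, col-175, bli-1, col-63, rol-1 and mab-10 held when any 1 late hour was left out. That of mab-3 ended without 34 h (−2.09, adjusted p = 0.0616). The call of lin-29 ended without 30, 32, 34 or 36 h, with the highest adjusted p at 0.194 without 34 h (−0.81). Without 36 h the calls of col-184 (adjusted p = 0.291), col-122 (0.335), col-124 (0.343), col-38 (0.177), col-71 (0.167) and sax-2 (0.204) ended, as did that of pgp-5 without 30 h (0.22). The gene col-60 was tested without 28, 30 or 32 h only, and its call held. Lists of small shifts that passed the preset test had no called gene: hedgehog-related genes (0 of 45, median −0.28, adjusted p = 0.000192; adjusted p = 0.471 with an estimated correlation), with grl-14 at −0.96 and wrt-8 at −1.02. The others were ribosomal protein genes (0 of 77, median −0.04, adjusted p = 0.00567; adjusted p = 0.789 with an estimated correlation) and histones (0 of 30, median −0.13, adjusted p = 0.00076; adjusted p = 0.186 with an estimated correlation). Larval collagens (adjusted p = 0.185), molting genes (0.103), seam cell genes (0.277), vulval genes (0.277), vitellogenins (0.671) and germline genes (0.281) did not pass.

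**Figure D2:**
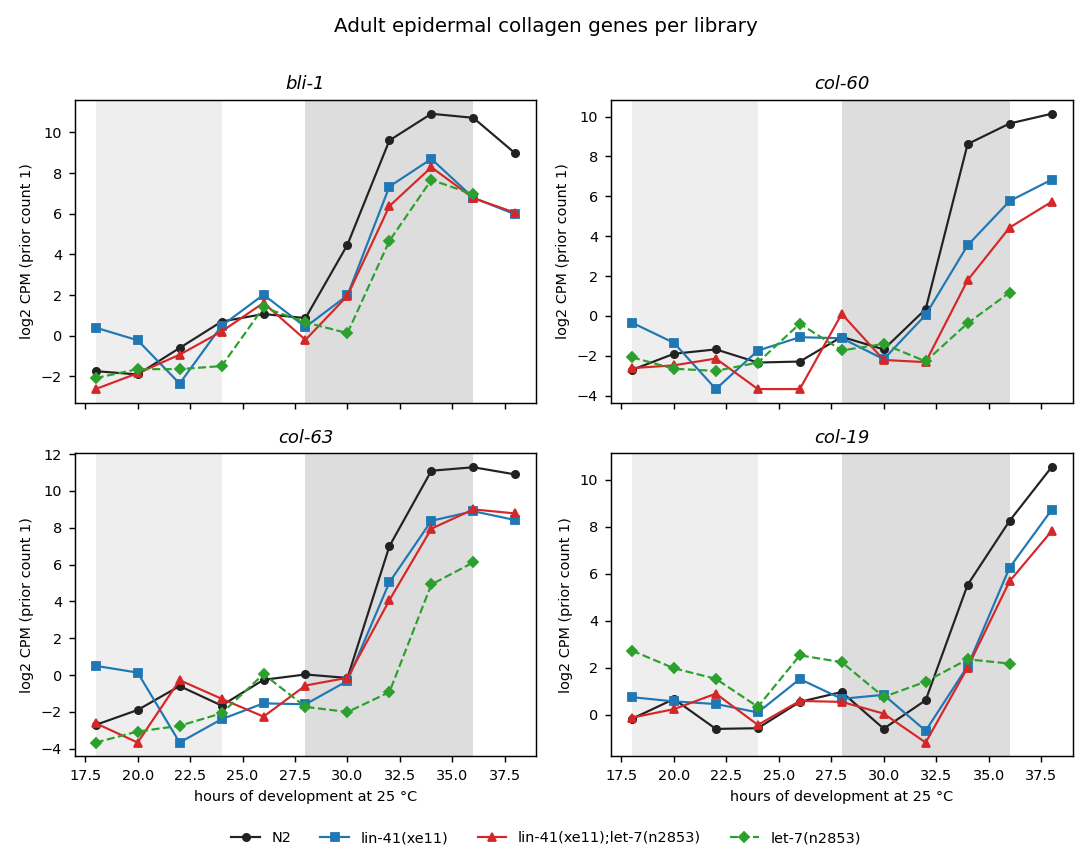
Footprint levels of bli-1, col-60, col-63 and col-19 in each library, as log2 CPM against the hour, with shading and dashes as for lin-41. Their levels in N2 climb steeply after 30 h.

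In the double mutant, daf-12 (chromosome X, 10635908 to 10666875) rose 3.35-fold over N2 in the late window (1.74 ± 0.13, adjusted p = 8.13e-07, n = 5), from 9.58 ± 3.2 to 32.1 CPM, while lin-41(xe11) stood at 9.27. The early means were 54.8 CPM in N2 and 57.3 in the double mutant. The let-7 family candidate hbl-1 (X, 5822142 to 5827755) rose by 0.96 ± 0.12 (adjusted p = 0.000133), and lin-14 was not called (0.34, adjusted p = 0.153). With lin-41, 3 of 10 candidates rose, and the list passed in both tests (adjusted p = 8.96e-08, and 0.000775 with an estimated correlation). The list holds lin-41, whose let-7 sites xe11 changes, and it was not tested without lin-41. This result therefore does not speak for the other candidates alone. The LIN41 targets fell as in lin-41(xe11): mab-10 by −1.17 ± 0.18 (adjusted p = 0.00173, to 5.04 CPM), mab-3 by −1.85 ± 0.32 (adjusted p = 0.0049, to 1.55 CPM) and lin-29 by −0.95 ± 0.16 (adjusted p = 0.00553, to 7.87 CPM). Their list passed as well (adjusted p = 6.2e-06; adjusted p = 0.00589 with an estimated correlation).

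The yolk protein genes vit-6 (−4.11 ± 0.37, adjusted p = 3.47e-06), vit-2 (−3.23 ± 0.30, adjusted p = 3e-05) and vit-1 (−0.80 ± 0.13, adjusted p = 0.00299) fell in the double mutant. Vitellogenins are made in the adult hermaphrodite intestine, and all 3 measurable members fell (list adjusted p = 1.18e-07; adjusted p = 0.00285 with an estimated correlation); vit-3, vit-4 and vit-5 were below the filter. Among the genes named by the rule collagens had the lowest values, though no list of all collagens was tested. They were col-120 (−6.22 ± 0.51, adjusted p = 2.59e-06, with 237 CPM in late N2, 3.14 in the double mutant and 12.8 in lin-41(xe11)) and col-88 (−5.61, adjusted p = 4.2e-05). Also lower were col-181 (−5.0, adjusted p = 0.000432), col-106 (−4.47, adjusted p = 0.000657), col-184 (−4.17, adjusted p = 0.00156), col-175 (−3.92, adjusted p = 3.47e-06), bli-1 (−3.15 ± 0.29, adjusted p = 5.36e-06) and col-49 (−2.36, adjusted p = 0.0045). Without both 34 and 36 h col-181 stood at −1.03, col-106 at −1.16 and col-184 at −0.62 (each adjusted p = 0.992), and vit-6 at −2.65 (adjusted p = 0.404). Matched by estimated age, with limma, col-120 stood at −3.24 (adjusted p = 0.112) and col-88 at −2.68 (adjusted p = 0.206). Adult epidermal genes fell in 6 of 7 cases (median −2.36, adjusted p = 8.29e-09; adjusted p = 0.0196 with an estimated correlation). Genes that rose were the monooxygenase fmo-4 (1.16 ± 0.25, adjusted p = 0.0256), the cytochromes P450 cyp-13A2 (0.80 ± 0.12, adjusted p = 0.00124) and cyp-37A1 (0.70 ± 0.15, adjusted p = 0.0267), the insulin-like ins-35 (0.70 ± 0.14, adjusted p = 0.0168), acs-7 (0.59, adjusted p = 0.0182), dhs-20 (0.44, adjusted p = 0.0378) and the potassium channel kvs-5 (0.38, adjusted p = 0.00815), whose early mean was 70.7 CPM against 56.4 in N2 (0.31, adjusted p = 0.262).

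Of 13508 genes 123 were called in the double mutant, 36 higher and 87 lower. The count was 59 without 32 h, 45 without 34 h, 36 without 36 h and 7 without both 34 and 36 h. It was 43 when matched by estimated age, 71 from the deposited log2 table, 4 without the hour term and 329 with wider windows. Calls of daf-12, lin-41, hbl-1, cyp-13A2, col-88, vit-6, col-175, vit-2, bli-1 and mab-10 held when any 1 late hour was left out. The call of mab-3 ended without 32 or 34 h (highest adjusted p = 0.0892). Without 34 h the calls of lin-29 (adjusted p = 0.0774), fmo-4 (0.246), ins-35 (0.0892), cyp-37A1 (0.246), acs-7 (0.194), dhs-20 (0.3), kvs-5 (0.0864) and col-49 (0.0839) ended. Without 36 h the same held for those of col-181 (0.0501), col-106 (0.066) and col-184 (0.144). The gene col-120 was tested without 28, 30 or 32 h only, and its call held. Lists without a called gene passed the preset test only: hedgehog-related genes (0 of 45, median −0.34, adjusted p = 4.8e-07; adjusted p = 0.246 with an estimated correlation), with wrt-8 at −1.48 and grl-27 at −1.46. The others were larval collagens (0 of 15, adjusted p = 0.0281; adjusted p = 0.542 with an estimated correlation), spermatogenesis genes (0 of 19, adjusted p = 0.0474; adjusted p = 0.199 with an estimated correlation) and, upward, ribosomal protein genes (0 of 77, median 0.07, adjusted p = 1.04e-07; adjusted p = 0.542 with an estimated correlation). Molting genes (0.0566), the heterochronic list (0.0593), intestinal genes (0.147) and germline genes (0.45) did not pass.

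**Figure D3:**
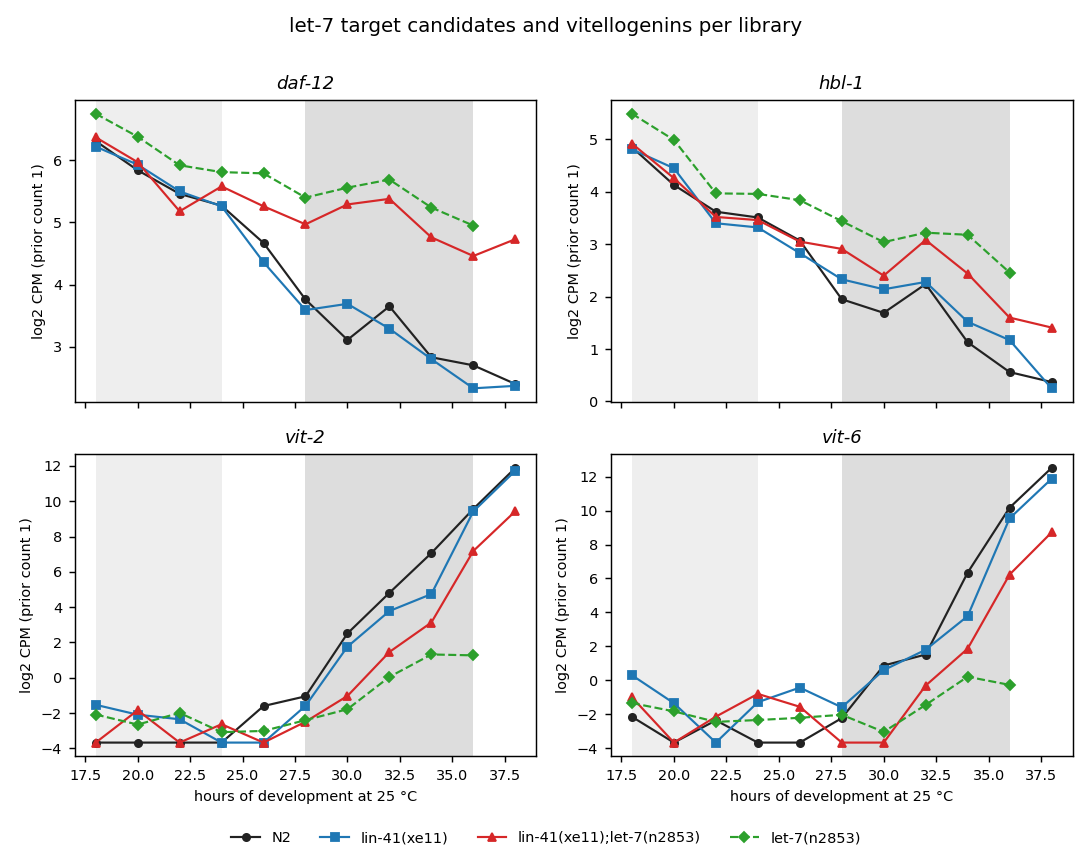
Footprint levels of daf-12, hbl-1, vit-2 and vit-6 in each library, as log2 CPM against the hour, with shading and dashes as for lin-41.

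Both lin-41(xe11) and the double mutant carry xe11, and they differ in the let-7 allele. Against the double mutant, daf-12 was lower in lin-41(xe11) by −1.81 ± 0.13 (adjusted p = 4.91e-07) and hbl-1 by −0.61 ± 0.11 (adjusted p = 0.0307), with n = 5 late libraries each. The let-7 candidate list passed downward with 2 of 10 genes (adjusted p = 1.38e-05; adjusted p = 0.00247 with an estimated correlation), and so did the heterochronic list with 2 of 16 (adjusted p = 0.00349; adjusted p = 0.0208 with an estimated correlation). Vitellogenins were higher in lin-41(xe11) in 3 of 3 cases: vit-6 by 2.94 ± 0.37 (adjusted p = 0.000616), vit-2 by 2.1 ± 0.30 (adjusted p = 0.00752) and vit-1 by 1.19 ± 0.13 (adjusted p = 0.000145; list adjusted p = 1.33e-09; adjusted p = 0.0015 with an estimated correlation). At 36 h vit-2 stood at 755 CPM in N2, 683 in lin-41(xe11), 145 in the double mutant and 2.33 in let-7(n2853), and vit-6 at 1150, 745, 74.9 and 0.751. Against N2, vit-2 (−1.13, adjusted p = 0.115), vit-6 (−1.17, adjusted p = 0.144) and vit-1 (0.39, adjusted p = 0.304) were not called in lin-41(xe11) over all genes. When adjusted over the list alone all 3 passed, vit-2 and vit-6 lower and vit-1 higher. The LIN41 targets were not called between the 2 strains (mab-10 −0.10, mab-3 −0.31, lin-29 0.08; list adjusted p = 0.886), nor did adult epidermal genes pass (adjusted p = 0.0982).

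Other genes higher in lin-41(xe11) than in the double mutant were the scramblase scrm-4 (1.03 ± 0.09, adjusted p = 1.57e-05; early means 10.6 and 6 CPM), timm-17B.2 (0.59, adjusted p = 0.0198; early means 3.45 and 2.22 CPM) and the GABA transporter snf-11 (adjusted p = 0.0198). Lower were nas-3 (−1.25 ± 0.22, adjusted p = 0.0243), cyp-13A2 (−0.86 ± 0.12, adjusted p = 0.00191) and ins-35 (−0.72, adjusted p = 0.0492). In all, 17 of 13508 genes were called, 10 higher and 7 lower. The count was 9 without 28 h, 8 without 32 h, 10 without 34 h and 7 without 36 h. It was 5 without both 34 and 36 h, 4 when matched by estimated age, 5 without the hour term, 28 with DESeq2 and 34 with wider windows. Calls of daf-12, vit-1, scrm-4 and cyp-13A2 held when any 1 late hour was left out. Over all alternatives run, the call of vit-1 ended in 2 and that of cyp-13A2 in 3, and those of daf-12 and scrm-4 in none. That of vit-6 ended without 36 h (2.46, adjusted p = 0.357) and that of vit-2 without 32 h (2.06, adjusted p = 0.0907). The calls of hbl-1 (adjusted p = 0.283), nas-3 (0.233) and ins-35 (0.283) ended without 32 h, that of timm-17B.2 without 34 h (0.224) and that of snf-11 without 28 h (0.154). Lists without a called gene passed the preset test only: ribosomal protein genes downward (0 of 77, adjusted p = 4.76e-22), intestinal genes downward (0 of 14, median −0.08, adjusted p = 0.00349), germline genes upward (0 of 24, adjusted p = 0.0416) and histones downward (0 of 30, adjusted p = 0.0445), each with an adjusted p = 0.419 with an estimated correlation, and spermatogenesis genes upward (0 of 19, adjusted p = 0.0281; adjusted p = 0.185 with an estimated correlation).

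In let-7(n2853), the late minus early difference to N2 was called for daf-12 (1.66 ± 0.15, adjusted p = 0.00645), for H04M03.3 (2.81, adjusted p = 0.0245) and, downward, for the ADP/ATP carrier gene ant-1.4 (−2.21, adjusted p = 0.0274). The level of daf-12 was 76.7 CPM early and 41.9 late in let-7(n2853), against 54.8 and 9.58 in N2. The values of hbl-1 (0.95 ± 0.21, adjusted p = 0.283), mab-10 (−1.74 ± 0.67, adjusted p = 0.416), mab-3 (−2.54 ± 0.82, adjusted p = 0.363) and lin-29 (−1.40 ± 0.36, adjusted p = 0.298) were not called over all genes. The 3 LIN41 targets, which stood late at 3.17, 0.907 and 5.75 CPM in the order mab-10, mab-3, lin-29, passed when adjusted over the list alone. This was not particular to them: vitellogenins passed in 3 of 3 cases and ribosomal protein genes in 59 of 77, all lower. Of let-7 family candidates 3 were higher and 1 lower, of the heterochronic list 4 and 2, and 4 of 15 larval collagens were higher. Only 3 of 13061 genes were called, 2 higher and 1 lower, and 1362 had an unadjusted p under 0.05. The count was 0 without 18 h (daf-12 1.65, adjusted p = 0.053) and 1 without 20, 22, 30, 32 or 34 h. That 1 call was daf-12, so the calls of H04M03.3 and ant-1.4 ended in each of these fits. After thinning of the let-7(n2853) counts to the median N2 total the count was 1 as well. In 3 alternatives the count was higher: 58 genes with DESeq2 (43.1% higher), 84 with all 4 strains in one fit (29.8% higher) and 18 when matched by estimated age (38.9% higher), so the number of genes depends on the method. In this comparison genes changed 2-fold were recovered in 47% of cases in simulated data, against 73 to 87% in the other strain comparisons.

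The preset list test passed 11 lists in let-7(n2853), and the test with an estimated correlation passed 0. These were LIN41 direct targets (downward, adjusted p = 0.000287; adjusted p = 0.178 with an estimated correlation), let-7 family candidates (upward, adjusted p = 0.00015; 0.0801), vitellogenins (downward, adjusted p = 1.33e-05; 0.165), adult epidermal genes (downward, median −3.12, adjusted p = 0.0381; 0.401) and larval collagens (upward, median 0.82, adjusted p = 3.76e-08; 0.312), with dpy-10 at 1.10 and dpy-7 at 1.07. Upward too were molting genes (adjusted p = 0.000368; adjusted p = 0.312 with an estimated correlation) and cell cycle genes (adjusted p = 0.00322; 0.353). Downward were spermatogenesis genes (adjusted p = 0.0302; adjusted p = 0.312 with an estimated correlation), ribosomal protein genes (median −0.36, adjusted p = 1.38e-31; 0.312), translation factors (adjusted p = 0.017; 0.379) and histones (adjusted p = 0.0025; 0.312).

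The direct differences of let-7(n2853) to N2 were far more numerous and cannot be separated from the time course and the purification. In the early window 3023 genes were higher and 2595 lower, and in the late window 3070 and 2989. The lists given next for the early window went the opposite way late minus early. Their late minus early results therefore cannot be read as late changes alone. Early, ribosomal protein genes were higher in 58 of 77 cases (adjusted p = 1.08e-12), translation factors in 10 of 17 (adjusted p = 0.0229), larval collagens lower in 8 of 15 (adjusted p = 0.00439) and molting genes lower in 7 of 25 (adjusted p = 0.0363), each with an adjusted p = 0.699 with an estimated correlation. Histones were higher in 21 and lower in 1 of 30 cases (adjusted p = 3.38e-07; adjusted p = 0.554 with an estimated correlation).

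**Figure D4:**
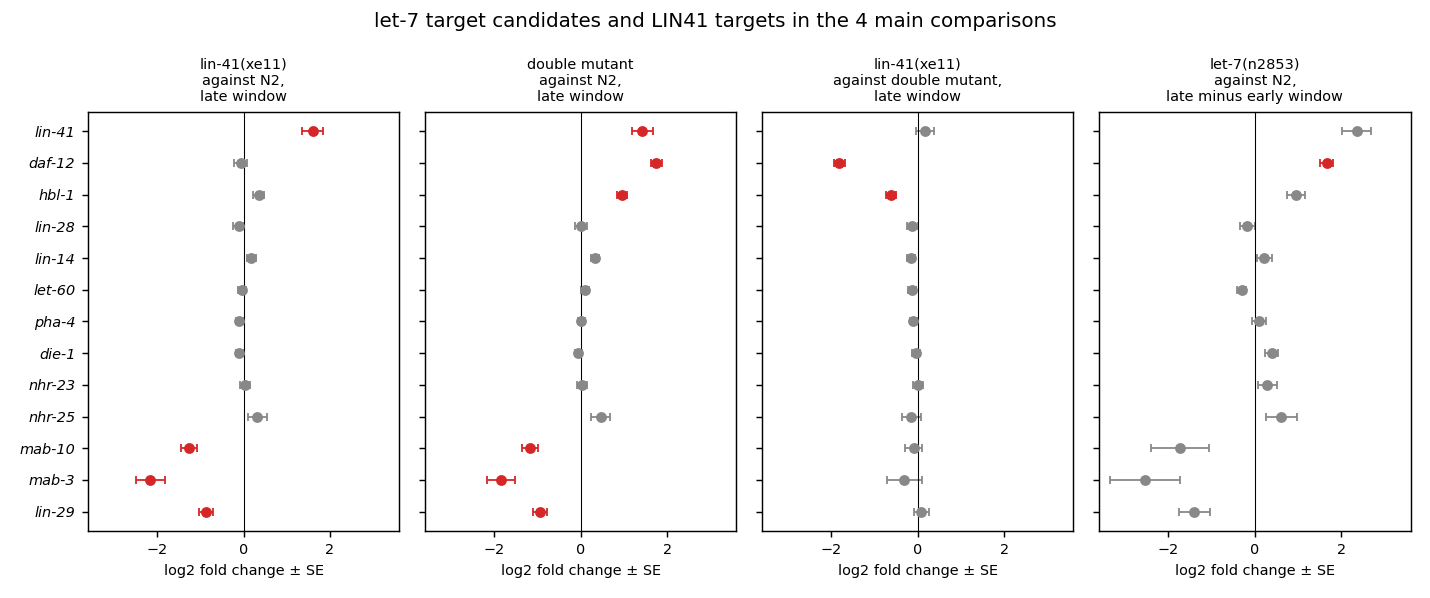
Log2 fold changes with standard errors of lin-41, the LIN41 direct targets and the let-7 family candidate targets in the 4 strain comparisons. Red marks an adjusted p under 0.05.

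The let-7 allele was compared in 2 backgrounds that share no library: with N2 alleles of lin-41 (let-7(n2853) against N2, late minus early) and with xe11 (the double mutant against lin-41(xe11), late). Of all genes only daf-12 was called higher with n2853 in both (expected by chance 0.00107), and 0 were called lower in both (expected 0.000768). Of the 17 genes called between lin-41(xe11) and the double mutant, 15 had the same direction with n2853 in both backgrounds. Among these 15, F52B10.3 (−0.04), scrm-4 (−0.08) and Y39G8B.7 (0.16) were close to no difference in let-7(n2853). In its late window alone timm-17B.2 had the opposite direction (1.34), so the count of directions is weak evidence of a shared effect. The 7 genes higher in the double mutant had a median of 0.68 in let-7(n2853), 6 of them above 0 (camera p = 5.34e-06; p = 0.0307 with an estimated correlation). The 10 lower genes had a median of −0.48, 1 of them above 0 (p = 2.11e-05; p = 0.0129 with an estimated correlation). Over 13028 genes the 2 differences correlated weakly (Pearson r = 0.16, Spearman rho = 0.086, 52.6% with the same sign).

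The effects of lin-41(xe11) and of the double mutant share the N2 libraries. Of their calls, 39 lower genes were common to both and 3 higher genes, lin-41 among them. Common N2 libraries raise this overlap, and no value that allows for them was computed for it. Their log2 fold changes correlated with r = 0.66, against 0.509 in 20 simulations without a strain effect. With the hours split between the strains, so that they shared no N2 library, r was 0.211. Such a split also rests each effect on different and fewer hours. The split values here and below therefore do not show what sharing N2 alone adds. The covariance was 0.0484, against 0.024 simulated and 0.0275 split, and 71.7% of genes had the same sign, against 66.8% simulated and 54.6% split. For lin-41(xe11) and let-7(n2853), which share N2 as well, r was 0.363 against 0.372 simulated and 0.119 split, and 61.1% had the same sign against 62% simulated and 53.5% split. Their covariance was 0.0393, against 0.0241 simulated and 0.0175 split, so the correlation alone does not decide whether the strains share an effect.

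Before lin-41 falls, the second-course strains were close to N2. In lin-41(xe11) the sequence-named K09C6.9 rose (1.10) and the immunoglobulin gene zig-2 (−1.17) and T26H5.9 (−1.07) fell in the early window, and zig-2 stood at −1.11 late. In the double mutant K09C6.9 rose (0.89), and zig-2 (−1.75 early, −0.95 late), F59F4.3 (−1.03), scrm-4 (−0.85) and mrpl-51 (−0.36) fell. The early counts were 3 of 13508 genes in lin-41(xe11) (774 at an unadjusted p under 0.05) and 5 in the double mutant (890). The late minus early difference to N2 passed for daf-12 (1.70 ± 0.17, adjusted p = 0.000201) and hbl-1 (0.96 ± 0.15, adjusted p = 0.0282) in the double mutant. In lin-41(xe11) edgeR called 0 genes late minus early. Of the 13508 genes 676 had an unadjusted p under 0.05, about as many as that threshold gives without any effect. No effect of lin-41(xe11), that on lin-41 included, was thus shown to differ between the windows, and its late calls are not shown to be specific to the late window.

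Estimated developmental age of let-7(n2853) lay 0.6 to 1 h below the sampled hour in 8 of its 10 libraries. The largest error of 0.3 h came from libraries simulated from the N2 course itself. It leaves out differences between cultures and purifications. Late libraries ran from −0.5 to 0.8 h around the hour in lin-41(xe11) and from −0.5 to 0.7 h in the double mutant. The age of let-7(n2853) is confounded with its separate time course. Late differences of let-7(n2853) to N2, in either direction, are read with these limits. In the late window the age exceeded the hour by 0.24 ± 0.47 h in lin-41(xe11) (mean ± SD, n = 5) and by 0.04 ± 0.53 h in the double mutant, and stood at −0.62 ± 0.48 h in let-7(n2853). The early values were 0.3 ± 0.48, −0.35 ± 0.24 and −0.52 ± 0.43 h (n = 4). With a period of 8 h, limma called 254 rhythmic genes in N2, 2401 in lin-41(xe11), 0 in the double mutant and 3246 in let-7(n2853), and 2711, 4105, 3888 and 4889 at an unadjusted p under 0.05. These counts depend on the setting. At a period of 7 h they were 541, 3483, 4126 and 4345, and at 9 h 0 in each strain, with 931, 951, 378 and 715 at an unadjusted p under 0.05. The 378 of the double mutant are fewer than that threshold gives without any rhythm. Over 18 to 38 h they were 1050 in N2, 3158 in lin-41(xe11) and 2426 in the double mutant. Amplitudes were compared over the 183 to 184 genes called rhythmic in N2 with a log2 amplitude of at least 0.5. Over these the double mutant had the highest median log2 amplitude (1.2, against 0.82 in N2, 0.99 in lin-41(xe11) and 1.09 in let-7(n2853)), though 0 of them were called in it. Peaks of genes rhythmic in N2 were offset to N2 by a median of −0.28 h in lin-41(xe11), 0.10 h in the double mutant and 0.64 h in let-7(n2853), over 183 to 184 genes.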

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

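The tests of the vitellogenin pattern in this part were chosen after the result was seen. In let-7(n2853), the lin-29 difference to N2 at 18 h (0.99) lay far from the other 3 early hours (gap of 0.945 of the range). It was 1 of 50 groups of libraries checked in this way, and chance marks about 1 in 20 groups. The double mutant's difference to N2 changed between the early and the late window for daf-12 (1.70) and hbl-1 (0.96), by a test of the difference. The late effects of lin-41(xe11) and of the double mutant differed, again by a test, for daf-12 (−1.81), hbl-1 (−0.61), vit-1 (1.19), vit-2 (2.1) and vit-6 (2.94).

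Libraries at 26 and 38 h were outside the windows compared between strains, and some stood above N2 there. At 26 h lin-41 stood at 70.8 CPM in let-7(n2853), 46.3 in lin-41(xe11) and 49.2 in the double mutant, against 26.1 in N2. At 26 h daf-12 stood at 55.2 CPM in let-7(n2853) and 38.3 in the double mutant, against 25.3 in N2, and at 38 h at 26.4 in the double mutant, against 5.20 in N2. At 26 h hbl-1 stood at 14.3 CPM in let-7(n2853), against 8.32 in N2, and at 38 h at 2.57 in the double mutant, against 1.22 in N2.

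Vitellogenins were lower in the double mutant than in lin-41(xe11), although both carry xe11. A delay of the whole animal as the whole cause is argued against by the estimated ages. From 30 to 36 h these were 30.2, 32.3, 33.5 and 36.8 h in lin-41(xe11) and 30.3, 32.2, 33.5 and 36.7 h in the double mutant (28.4 and 27.5 h at 28 h). At matched age vit-1 (0.94, SD 0.63), vit-2 (1.78, SD 1.07) and vit-6 (2.48, SD 1.27) kept at least 83.9% of the hour-matched difference of mean log2 CPM (1.12, 1.97 and 2.74), each above its SD. With ages this close little could be lost, so that share decides nothing. None of the 3 was called in the age-matched limma fit (adjusted p = 1). That fit had no hour term, so it did not pair the 2 strains by hour. Whether this ended the calls was not tested. A delay of the intestine or of yolk genes alone would not show in an age from all genes and stays open. Less intestinal RNA in the double mutant is argued against too, since 14 intestinal genes had a median of −0.08 between the strains, opposite in sign to the vitellogenins. The let-7 allele, as the biological explanation, could lower vitellogenins, and at matched age the means of vit-1 (−0.87, SD 0.74), vit-2 (−4.30, SD 2.11) and vit-6 (−3.69, SD 3.33; 4 of 5 hours lower) lay below N2 in let-7(n2853) late. It stays open because let-7(n2853) comes from the other time course and purification and because vit-1 missed the bound of 1, and reads shared between vitellogenin copies were not tested.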

How the results depend on the processing

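Leaving out 34 and 36 h together, and each early hour, was chosen after the data were seen. No called direction among the named genes reversed. Of 1850 alternative values over 111 results 1537 stayed on their side of the threshold, 304 lost a call and 9 gained one. Counts of calls below are in the order lin-41(xe11) against N2, double mutant against N2, lin-41(xe11) against the double mutant, let-7(n2853) late minus early, and N2 late against early (56, 123, 17, 3 and 1944).

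RLE scaling gave 55, 122, 18, 3 and 1947, library totals 55, 105, 16, 3 and 2487, and no filter 61, 116, 17, 3 and 2167. Library totals shifted the median of all genes in N2 by −0.176 and took the share of higher genes from 50.6 to 28.1%; no filter took it to 64.6%. A filter of 5 CPM gave 39, 14, 1 and 1356 in the comparisons other than the double mutant against N2, where it kept 102 of the calls. It tests fewer genes. DESeq2 gave 53, 156, 28, 58 and 2622, and all 4 strains in one fit 45, 95, 18 and, for let-7(n2853), 84. Without the hour term, which leaves the change over time in the residual, edgeR called 3, 4, 5 and 0 (523 at an unadjusted p under 0.05). In each of these comparisons fewer genes had an unadjusted p under 0.05 than that threshold gives without any effect. Windows of 18 to 26 h and 28 h to the last hour gave 138, 329, 34, 2 and 3009, with more libraries. A late window of 30 to 36 h, the same fit as that without 28 h and counted above under both, gave 58, 145, 9, 2 and 2057. Matching by estimated age with limma had no hour term and took the interpolated N2 course as free of error. It gave 17, 43, 4 and 18, which are not directly comparable with the main counts. The deposited log2 table with limma gave 16, 71, 13 and 2. In these 2 alternatives the share of higher genes rose from 9 of 56 to 52.9 and 43.8% in lin-41(xe11) and from 29.3% to 67.4 and 47.9% in the double mutant. Except where fewer or more libraries or genes or the missing hour term account for it, the cause was not tested.

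Leaving out 1 hour gave from 13 to 58, 36 to 145, 7 to 15, 0 to 2 and 633 to 2057 calls. The 0, without 18 h, had 1038 genes at an unadjusted p under 0.05 in edgeR. Without 34 and 36 h the counts were 5 (4 of the same genes), 7 (7), 5 (4), 1 (0) and 82 (78), with fewer libraries, and 44 of 48, 114 of 115, 16 of 16, 2 of 2 and 1822 of 1822 tested calls kept their direction.

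Rhythmic genes in limma numbered 541 in N2 at a period of 7 h, 0 at 9 h (931 unadjusted), 433 with a prior count of 5 and 1050 over 18 to 38 h. They numbered 0 at 9 h in lin-41(xe11) (951 unadjusted) and in let-7(n2853) (715 unadjusted), and 4126 at 7 h and 2426 over 18 to 38 h in the double mutant; the cause was not tested. Among genes of at least 5 CPM the 2 let-7 backgrounds correlated with r = 0.281. Lists passing fell from 5 to 1, 8 to 4, 8 to 3, 11 to 0 and 13 to 0 with an estimated correlation; the cause was not tested. The 1 left in lin-41(xe11) was LIN41 direct targets, a list that may rest in part on these same libraries. Depth limits genes under 1 CPM, such as dmd-3, which were not tested.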

Other observations

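The tests of the adult epidermal pattern, and that of the let-7 allele for the early differences, were chosen after the result was seen; those of coding length, depth and other splits were not. Among genes rising with n2853 outside the fixed lists, H04M03.3 was called in let-7(n2853) (2.81 late minus early, adjusted p = 0.0245) and stood at 2.40 (adjusted p = 0.0944) in the double mutant late minus early. Its call in let-7(n2853) held when 28 h was left out and ended when any other single hour of the 2 windows was left out. In let-7(n2853) 9 of 10 let-7 family candidate targets were called higher than in N2 late and 6 of 10 already early, in a comparison confounded with the time course, so this is not specific to the late window.

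Adult epidermal genes were lower late in lin-41(xe11), where 5 of 7 were called (not bli-2 and col-62) and the list had an adjusted p = 0.103 with an estimated correlation, and in the double mutant, where 6 of 7 were called. A scaling shift from library size or composition is argued against, since it would move all genes alike. With library totals alone the list median was −2.02 in lin-41(xe11) and −2.33 in the double mutant, while that of all genes was 0.03 and 0.011. The change of scaling moves every gene by nearly the same small amount, so the list median itself could hardly change. Estimated ages at 34, 36 and 38 h were 33.5, 36.8 and 38 h in lin-41(xe11) and 33.5, 36.7 and 37.7 h in the double mutant. They argue against a delay of the whole animal by 2 h. A delay of these genes alone would not show in such ages and cannot be told apart for either part of the list. Libraries at 34, 36 and 38 h were set against N2 2 h earlier. The median for bli-1, bli-2, col-38, col-49 and col-63 was −1.56 (SD 1.67) in lin-41(xe11) and −1.48 (SD 1.41) in the double mutant. For col-19 and col-62 it was 0.89 (SD 0.73) and 0.66 (SD 0.95), and 3 hours of a steep rise are too few. At matched age every one of the genes was lower, with medians of −1.43 and −1.84 against −2.08 and −2.36 by hour. Raised lin-41 could lower them, and their median in let-7(n2853) was −3.12 late minus early, but with an estimated correlation p was 0.401 and the time course differs, so this stays open.

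Strain let-7(n2853) and N2 differed in 5618 genes already early; a batch difference between the 2 time courses or purifications could not be separated from the strain and stays open. Deeper sequencing of let-7(n2853) is argued against, since thinning to the N2 total left 90.8% as many calls (5099 of 5618). The let-7 allele is argued against as far as the xe11 background goes, where 3 genes were called early between lin-41(xe11) and the double mutant. Coding length was related to the early difference (Spearman rho = −0.28 over 12738 genes; median 0.27 in the shortest and −0.16 in the longest of 5 groups), which leaves a length bias between the purifications open as a part. As the whole cause it is argued against, since after a length trend was removed 4958 calls were made, 90.6% as many as before among these genes.

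In each comparison 100 of 126 splits were fitted, the real one included: splits of the late libraries between the strains, or, for let-7(n2853) and within N2, of the hours between the windows. For lin-41(xe11) against N2 the real split gave 56 calls and the highest other 46, and for the double mutant 123 and at most 84.6% as many. For lin-41(xe11) against the double mutant they gave 17 and 5, and for N2 late against early 1944 and 1738. Each time only 1 split, the real one, gave as many. In the 3 strain comparisons libraries are matched by hour, and only 14, 14 and 12 of the other splits drawn part every hour, with at most 23, 51 and 2 calls. These are too few for a share under 0.05. For the let-7(n2853) difference of differences 3 splits gave as many as the real 3 calls, and the highest other 6. Hours of a time series cannot be exchanged freely, so chance is not excluded by the splits of hours, in let-7(n2853) or in N2.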
